A study of Helianthus annuus with 12 samples.

How the data were processed

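RNA from 12 seed samples of Helianthus annuus was sequenced on an Illumina NovaSeq after extraction with the RNAprep pure Plant kit, per the labels' protocols. The samples were seeds of the cultivars 86-1 and L-1-OL-1 at 17 and 27 DAF, with 3 libraries per group. Groups and replicate numbers were taken from the labels, and each value column of the expression table was matched to a sample by its name, with 0 columns left unmatched. The authors deposited the expression values as FPKM, scaled by gene length and library size. HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5 are named, without a role or order, per the submitters' processing notes. The genome build, the gene annotation and any filter on the values are not given in the sources used here. No gene coordinates are printed, because 0 of the gene identifiers could be linked to the reference gene table.

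A second table deposited by the authors gives each gene's best match in a protein database named nr, with a match score and an E-value; the search tool is not given in the sources used here. Its descriptions named the genes and the score was not used further. It holds 65535 lines, the most a sheet of its kind takes, and 1021 gene models that sort after its last entry have 0 annotations, so it was read as incomplete. Of the 48882 genes with expression values 45957 had a description, as had 28801 of the 30020 tested genes. The expression table includes 11012 gene models that the authors added to the annotation, of which 5929 were tested. Genes with close relatives, such as storage proteins and histones, can share reads, and how these were divided is not given in the sources used here.

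FPKM values are not counts, so differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), and count-based tests were not run. Genes with an FPKM of at least 1 in at least 3 of the 12 libraries were tested. One model with a mean per group was fitted to all 12 libraries, so that the groups shared 1 estimate of the spread, with a mean-variance trend. The contrasts were 86-1 minus L-1-OL-1 at each stage, 27 minus 17 DAF in each cultivar, and the difference of these stage differences. P-values are 2-sided and were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05 and no fold minimum. No log2 difference is printed against a group listed at 0 in all its libraries. Depth was compared through the smallest steps between low FPKM values of the same gene, which gives relative depths only, so no counting interval could be given.

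Lists of genes were defined by words in the descriptions. They were omega-6, omega-3 and stearoyl-ACP desaturases, plastid fatty acid synthesis, acyl-ACP thioesterases with acyl-CoA synthetases, triacylglycerol assembly, oil body proteins, seed storage proteins, LEA and desiccation proteins, heat shock proteins, seed maturation regulators and lipid breakdown with the glyoxylate cycle. The others were lipoxygenases, carbon supply, glycolysis with pyruvate dehydrogenase, photosynthesis, cell cycle with histones, cytosolic ribosomal proteins, flavonoid synthesis, secondary wall and lignin, cuticle and wax, endosperm and seed coat, the abscisic acid pathway and tocopherol synthesis. Wall, cuticle, and endosperm and seed coat lists served as markers of tissues other than the embryo. The 21 lists with at least 3 tested members were tested with limma's camera at its preset correlation of 0.01, adjusted over the 105 tests of all lists and contrasts. The same test with an estimated correlation, and fry, were alternatives. List medians are given relative to the median of all tested genes, which was 0.00466 and -0.12 for the cultivar differences at 17 and 27 DAF, -0.20 and -0.00125 for the stage differences in 86-1 and L-1-OL-1, and -0.23 for the interaction. Median-of-ratios scaling moved the medians at 27 DAF, in 86-1 and in the interaction to 0.08, -0.03 and -0.03, and quantile normalization moved that in 86-1 to 0.000272. Medians set beside a mean and the direction of a test are the list's own.

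The genes named in the text follow a rule. It takes, per contrast, the 6 largest positive and 6 largest negative differences among called genes with a mean FPKM of at least 10 in the higher group, no overlap between the groups' libraries and a description that names a protein. It also takes up to 3 called members of each list with at least 3 calls or a list call, and all tested omega-6 and stearoyl-ACP desaturases. Non-overlap of 3 against 3 libraries has a chance of 10%. The rule named 197 genes, and 111 of them are printed with the comparisons, chosen within the rule after their values were seen and mostly for keeping their calls without single libraries. Over all genes the rule named, the calls that held in every fit without 1 library were 36 of 66 at 17 DAF, 56 of 71 at 27 DAF, 47 of 66 in 86-1, 52 of 66 in L-1-OL-1 and 44 of 62 in the interaction. The contrasts, tests, filter, lists, rule and most alternatives were chosen before the data were examined.

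The alternatives were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, equal library totals, median-of-ratios scaling, quantile normalization, no trend, only the libraries of a contrast, the replicate number as a block and each library left out in turn. A fit without L-1-OL-1 17 DAF replicates 2 and 3 and a fit with each library's mean LEA level as a covariate were added after the data were seen. Simulated data had 100 of 30020 genes changed per size, far fewer than called here, so recovery at the data's looser cutoff was not tested. Recovered, in the contrasts' order, were 54%, 62%, 71%, 63% and 20% of 4-fold and 3%, 3%, 16%, 8% and 0% of 2-fold changes. Tables used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.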

Results

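Gene expression was measured by RNA sequencing in seeds of the sunflower cultivars 86-1 and L-1-OL-1, collected 17 and 27 days after flowering (DAF). The labels present the series as a comparison of seed development in sunflowers with high and low oleic acid content. They describe 17 DAF as a stage of fast oleic acid accumulation and 27 DAF as a stage at which it stayed about level. They do not say which cultivar has the high content, so the groups are named by cultivar and stage only. Each of the 4 groups held 3 libraries, numbered 1 to 3. No label says that the libraries of a group came from separate plants, so the p-values measure only the spread between these libraries.

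The deposited values were FPKM (fragments scaled by gene length and by the number of mapped fragments) for 48882 genes, of which 30020 were tested. FPKM totals lay between 605655 and 683903 per library. Read numbers are unknown from such values, and the steps between low FPKM values put the relative depth of the libraries between 0.796 and 1.22 times that of replicate 1 of 86-1 at 17 DAF. Gene levels are given as mean FPKM ± SD of 3 libraries. Differences are log2 differences ± standard error on the log2(FPKM + 1) scale, which understates the change of genes with low values. Gene names are the deposited identifiers, and what each gene encodes is its best database match in the deposited annotation.

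The first principal component of the log2 values held 54.7% of the variance. It placed 86-1 at 17 DAF at one end (scores of -151 to -120.0) and L-1-OL-1 at 27 DAF at the other (178 to 179). Across genes, libraries of a group had Pearson's r of 0.931 to 0.974 outside L-1-OL-1 at 17 DAF. Replicate 1 of that group had r of 0.833 to 0.860 with 86-1 at 17 DAF. It had 0.861 and 0.784 with its group's replicates 2 and 3, themselves at 0.945 (genes are not independent replicates). Genes of seed storage proteins took 31.0%, 18.5% and 0.962% of the FPKM total in replicates 1, 2 and 3 of this group, and 31.5%, 9.63% and 9.22% in those of 86-1 at 17 DAF. Genes of late embryogenesis abundant (LEA) proteins, which protect drying seeds, took 0.610%, 1.72% and 4.57% in L-1-OL-1 at 17 DAF. The LEA shares were 0.372% to 0.646% in 86-1 at 17 DAF, 2.59% to 4.93% in 86-1 at 27 DAF and 5.79% to 8.02% in L-1-OL-1 at 27 DAF.

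**Figure D1:**
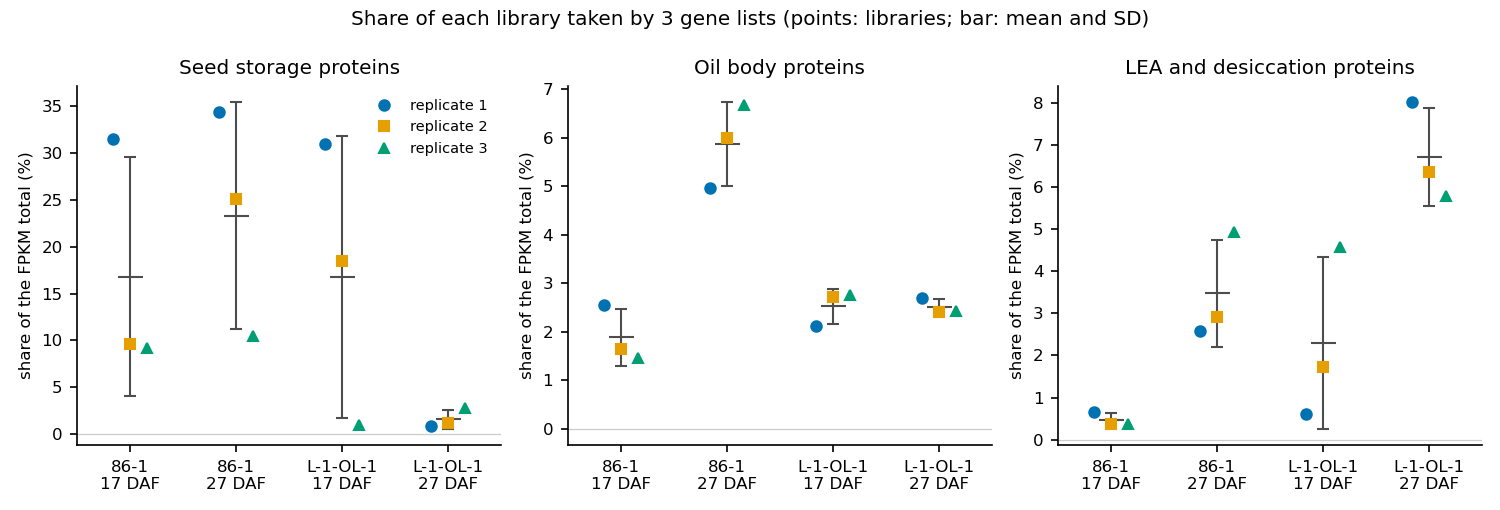
Share of the FPKM total (%) taken by the genes of 3 lists in each of the 12 libraries, by cultivar and days after flowering; points are libraries and bars give the mean and SD of 3 libraries. Storage protein genes took 0.852% to 2.75% in L-1-OL-1 at 27 DAF and 10.4% to 34.4% in 86-1 at 27 DAF, while the libraries of L-1-OL-1 at 17 DAF ranged from 0.962% to 31.0%.

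At 17 DAF the comparison of the cultivars asked which genes differed while oleic acid was accumulating. The oleate desaturase gene64287 encodes the type of enzyme that turns oleic acid into linoleic acid. It was far higher in 86-1, with 695 ± 212 FPKM against 23.3 ± 23.8 in L-1-OL-1 (log2 difference 5.49 ± 0.76, adjusted p = 0.000169). The stearoyl-ACP desaturase gene3372, which makes the oleoyl chain from the stearoyl chain, was also higher in 86-1 (1191 ± 299 against 383 ± 495, 2.74 ± 0.93, adjusted p = 0.0469). So were the sucrose synthase gene45459, which opens the use of incoming sucrose (1494 ± 438 against 188 ± 259.8, 4.03 ± 0.83), and the enolase gene25883 (1385 ± 361 against 338 ± 203, 2.15 ± 0.44). The dehydrin gene55914 had 0.367 ± 0.27 FPKM in 86-1 and 355 ± 377 in L-1-OL-1 (-6.49 ± 1.23), and the oleosin gene11149 had 1.02 ± 1.15 and 419 ± 530.1 (-5.81 ± 1.44, a call lost in a fit of these 6 libraries alone, adjusted p = 0.0591).

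Of the 5 tested omega-6 desaturase genes, 3 were higher in 86-1 and none lower at 17 DAF (camera adjusted p = 0.0805), and the same number passed when adjusted over the list alone. Besides gene64287 these were gene18808 (254 ± 282 against 10.5 ± 17.7, 4.53 ± 1.49) and gene55389 (26.7 ± 17.2 against 4.78 ± 1.05, 2.0 ± 0.54). Its other members gene1458 and gene44739 had differences of 0.35 ± 0.81 and 0.16 ± 0.3 (adjusted p = 0.802 and 0.753). The stearoyl-ACP desaturase gene48724 had 0.53 ± 0.39 (adjusted p = 0.368), so that 1 of the 2 tested members of that list passed, and both without L-1-OL-1 replicate 1 (0.0192 for gene48724). The call of gene18808 was lost without replicate 2 or 3 of 86-1 (adjusted p = 0.148 and 0.172) or replicate 2 or 3 of L-1-OL-1 (0.147 and 0.149), and in 7 other settings (highest 0.149, in a fit of these 6 libraries). That of gene55389 was lost without replicate 2 or 3 of 86-1 (0.0714 and 0.0746) and in that fit (0.0503). That of gene3372 was lost without replicate 1, 2 or 3 of 86-1 (0.112, 0.114 and 0.0886) or replicate 2 or 3 of L-1-OL-1 (0.114 and 0.172), and in 6 other settings (highest 0.135, in that fit). The call of gene64287 held without any 1 library.

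In the list of acyl-ACP thioesterases and acyl-CoA synthetases, which release and activate fatty acids, 6 of 16 members were higher in 86-1 and 0 lower (8 and 0 adjusted over the list alone) at 17 DAF, with a median 0.98 above that of all genes. For the thioesterase and synthetase genes, camera gave an adjusted p = 0.004, and an adjusted p = 0.742 with an estimated correlation. The call was lost with only genes of a mean FPKM of at least 5 (adjusted p = 0.0687). The acyl-CoA synthetase gene43869 had 26.8 ± 1.39 FPKM in 86-1 against 9.93 ± 2.32 (1.37 ± 0.22), and gene28825 had 6.54 ± 0.32 against 0.0127 ± 0.0219 (2.9 ± 0.22). Plastid fatty acid synthesis gave no list call, and 6 of 26 members were higher in 86-1 and 3 lower (10 and 4 adjusted over the list alone) (camera adjusted p = 0.212). Its oxoacyl-ACP synthase Helianthus_annuus_newGene_24716 was lower in 86-1 (0.689 ± 1.07 against 9.51 ± 1.98, -2.79 ± 0.36). In triacylglycerol assembly 3 of 26 members were higher in 86-1 and 3 lower (3 and 2 adjusted over the list alone) (camera adjusted p = 0.445). There the glycerol-3-phosphate acyltransferase gene64602 was higher (2.61 ± 0.37) and its relative gene31133 lower (-2.94 ± 0.43) in 86-1.

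The list calls of cell cycle, ribosomal and photosynthesis genes at 17 DAF were lost without L-1-OL-1 replicates 2 and 3 (adjusted p = 0.813, 0.119 and 0.236), where 1 library of that group is left and the other groups give the spread. In the list of cell cycle and histone genes 102 of 243 members were higher in 86-1 and 12 lower (127 and 13 adjusted over the list alone), with a median 1.06 above that of all genes. For the cell cycle genes, camera gave an adjusted p = 5.67e-08, and an adjusted p = 0.833 with an estimated correlation. Examples were the histone H2B gene35308 (471 ± 247 against 101 ± 112, 2.62 ± 0.63) and the kinesin gene40816, at 58 ± 5.17 in 86-1 and 0.0375, 0 and 0 in the L-1-OL-1 libraries. Of the cytosolic ribosomal protein genes 14 of 79 members were higher in 86-1 and 3 lower (14 and 3 adjusted over the list alone), with a median of 0.84. For the ribosomal protein genes, camera gave an adjusted p = 6.32e-05, and an adjusted p = 0.833 with an estimated correlation. One of them was gene74529 of the large subunit (3.44 ± 0.36). In the photosynthesis list 2 of 79 members were higher in 86-1 and 18 lower (2 and 17 adjusted over the list alone), with a median of -1.44. For the photosynthesis genes, camera gave an adjusted p = 6.99e-07, and an adjusted p = 0.833 with an estimated correlation. They took 0.0205% to 0.0344% of the FPKM total in 86-1 and 0.0244%, 0.168% and 0.193% in replicates 1, 2 and 3 of L-1-OL-1. The Rubisco small chain gene46194 had 3.65 ± 1.23 against 23.8 ± 14.7 (-2.18 ± 0.55), a call lost without L-1-OL-1 replicate 2 (adjusted p = 0.0531). In the LEA list 8 of 69 members were higher in 86-1 and 19 lower (8 and 25 adjusted over the list alone), with a median of -0.93. For the LEA genes, camera gave an adjusted p = 0.00677, and an adjusted p = 0.833 with an estimated correlation.

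The remaining lists gave no call at 17 DAF. Among seed storage protein genes 4 of 40 members were higher in 86-1 and 8 lower (4 and 8 adjusted over the list alone) (camera adjusted p = 0.408). The seed storage albumin gene70268 (-4.48 ± 1.05) and the lipid-transfer-type proteins gene69051 (-3.03 ± 0.49) and gene2767 (-5.92 ± 0.49) were lower in 86-1. The median (0.52) and mean (0.11) of that list were above 0 while its test pointed down. Of the flavonoid genes 4 of 26 members were higher in 86-1 and 5 lower (4 and 6 adjusted over the list alone) (camera adjusted p = 0.786), with a median of 0.14, a mean of -0.11 and a test pointing down. The hydroxylase Helianthus_annuus_newGene_23641 was lower in 86-1 (-4.49 ± 0.31). For secondary wall and lignin, a mark of hull tissue, 19 of 45 members were higher in 86-1 and 10 lower (20 and 12 adjusted over the list alone) (camera adjusted p = 0.109). The cinnamyl alcohol dehydrogenase gene72132 (1.48 ± 0.28), the fasciclin-like protein gene32949 (3.19 ± 0.65) and the laccase gene31307 (5.41 ± 0.28) were higher. For oil bodies 3 of 31 members were higher in 86-1 and 8 lower (4 and 11 adjusted over the list alone) (camera adjusted p = 0.0736). In the heat shock list 8 of 130 members were higher in 86-1 and 23 lower (7 and 21 adjusted over the list alone) (camera adjusted p = 0.0695), with gene50700 lower (-3.88 ± 0.8). Of the lipoxygenases 2 of 13 members were higher in 86-1 and 3 lower (2 and 3 adjusted over the list alone) (camera adjusted p = 0.632), with gene57460 higher (3.47 ± 0.43) and gene57445 lower (-4.08 ± 0.91). In carbon supply 8 of 44 members were higher in 86-1 and 2 lower (7 and 2 adjusted over the list alone) (camera adjusted p = 0.626). The invertase Helianthus_annuus_newGene_6309 was at 7.77 ± 1.45 in 86-1 and listed at 0 in every L-1-OL-1 library. For glycolysis 30 of 113 members were higher in 86-1 and 10 lower (35 and 15 adjusted over the list alone) (camera adjusted p = 0.122). The pyruvate kinase Helianthus_annuus_newGene_36569 was at 8.71 ± 1.18 and likewise listed at 0 in L-1-OL-1.

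Beyond the lists, the legumain peptidase gene12508 (759 ± 407 against 8.63 ± 9.82, 6.63 ± 0.67) and the isoflavone reductase-like gene5766 (139 ± 81.9 against 0.379 ± 0.598, 6.51 ± 0.45) had large positive differences at 17 DAF. The glycine-rich protein gene18005 (4.97 ± 6.71 against 1074 ± 794, -7.74 ± 0.84) and the Kunitz-type proteinase inhibitor gene63167 (-6.11 ± 0.95) had large negative ones. In all, limma called 8111 of 30020 genes, 4685 higher and 3426 lower in 86-1, and 6587 of these differed at least 2-fold. The share of higher genes among the calls was 57.8%, and 46.9% without L-1-OL-1 replicate 1. The count was 12295 without that library, 5137 in a fit of these 6 libraries alone, 2300 with only genes of a mean FPKM of at least 5 and 4637 with the mean LEA level as a covariate. With replicate 1 as the only library of L-1-OL-1 it was 3768. Of the 33 called genes named here, 29 kept their call without any 1 library (mostly chosen for this), 27 in a fit of these 6 libraries (lost for gene35308 and gene70268, adjusted p = 0.0663 and 0.0502, among others) and 22 with the LEA covariate.

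**Figure D2:**
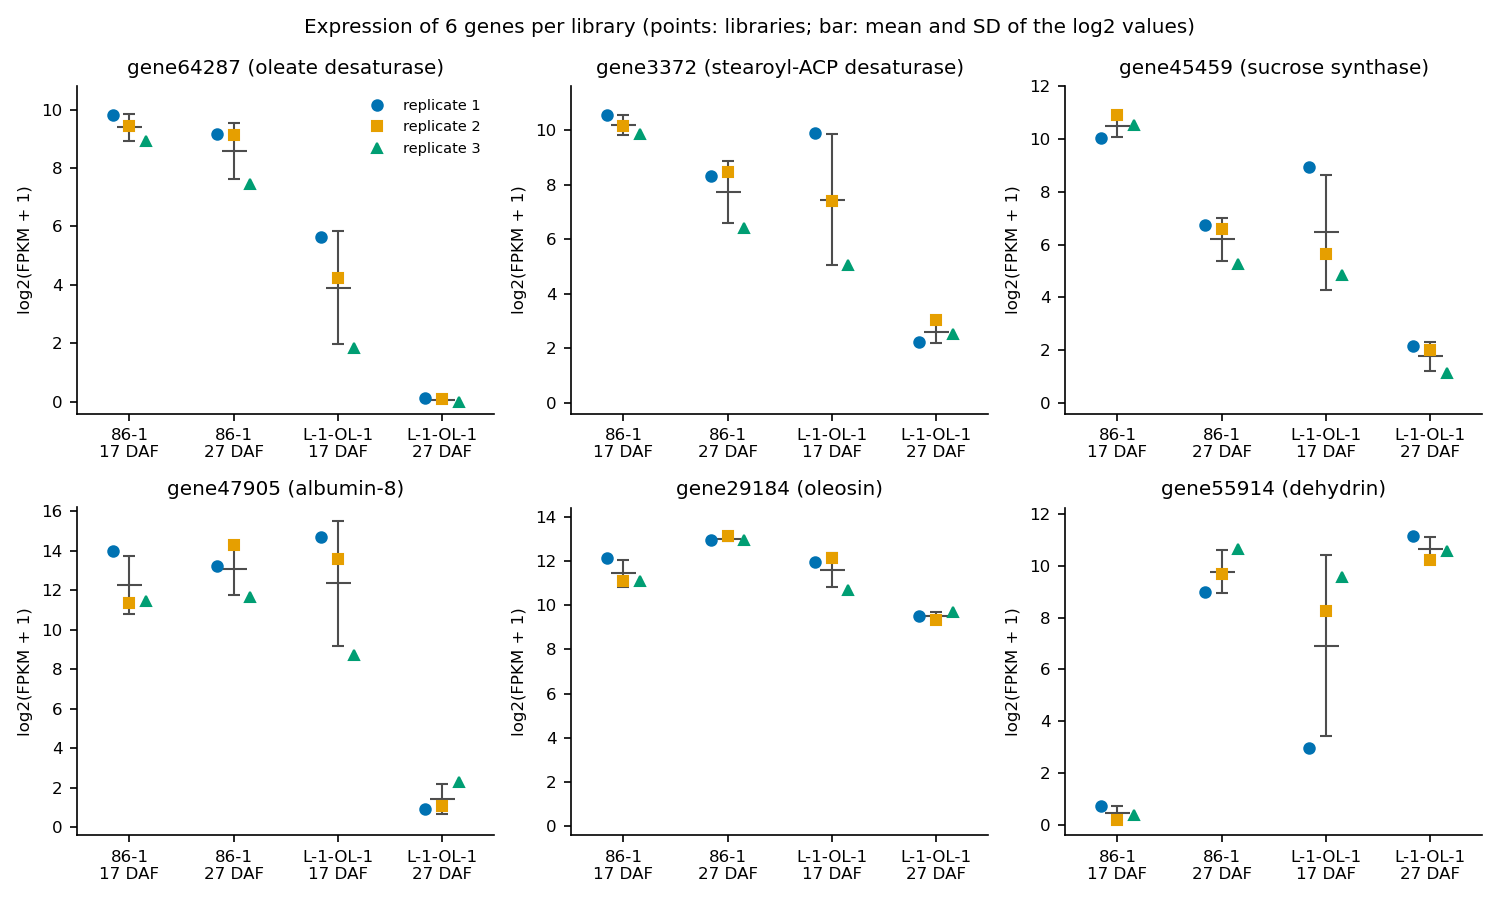
Expression of 6 genes as log2(FPKM + 1) in each of the 12 libraries, by cultivar and days after flowering; points are libraries and bars give the mean and SD of the log2 values of 3 libraries. The oleate desaturase gene64287 was at 481 to 905 FPKM in 86-1 and 2.55 to 49.3 FPKM in L-1-OL-1 at 17 DAF, and albumin-8 (gene47905) averaged 1.95 FPKM in L-1-OL-1 at 27 DAF.

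At 27 DAF the comparison asked which genes differed once oleic acid had stopped accumulating. The oleate desaturase gene64287 was at 433 ± 223 FPKM in 86-1 and 0.0546 ± 0.048 in L-1-OL-1, with values of 0.0902, 0.0735 and 0 (log2 difference 8.5 ± 0.76, adjusted p = 2.68e-06). Both tested stearoyl-ACP desaturase genes were higher in 86-1, gene3372 with 252 ± 146 against 5.16 ± 1.78 (5.15 ± 0.93) and gene48724 with 75.3 ± 19.4 against 11 ± 1.8 (2.64 ± 0.39). Of the storage proteins 25 of 40 members were higher in 86-1, among them the 11S storage protein gene16080 (32858 ± 19362 against 420.1 ± 305, 6.28 ± 1.2) and albumin-8, gene47905 (10886 ± 8438 against 1.95 ± 1.65, 11.63 ± 1.3). The ribosomal protein gene gene42404 was lower (135 ± 47.2 against 585 ± 116, -2.14 ± 0.35).

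Of the omega-6 desaturases, gene64287 alone passed at 27 DAF, over all genes and adjusted over the list alone (camera adjusted p = 0.521). The other members gene18808, gene55389, gene1458 and gene44739 had differences of 0.08 ± 1.49, 0.07 ± 0.54, -0.86 ± 0.81 and -0.23 ± 0.3, with adjusted p from 0.407 to 0.973. In the thioesterase and acyl-CoA synthetase list 10 of 16 members were higher in 86-1 and 0 lower (10 and 1 adjusted over the list alone), with a median 1.28 above that of all genes. For the thioesterase and synthetase genes, camera gave an adjusted p = 0.00261, and an adjusted p = 0.742 with an estimated correlation. Its member gene43869 had 16.4 ± 0.753 against 0.384 ± 0.15 (3.66 ± 0.22) and gene1412 8.32 ± 3.19 against 0.0158 ± 0.0274 (3.14 ± 0.26). For plastid fatty acid synthesis 12 of 26 members were higher in 86-1 and 3 lower (12 and 3 adjusted over the list alone). For the fatty acid synthesis genes, camera gave an adjusted p = 0.0497, and an adjusted p = 0.833 with an estimated correlation. The acyl carrier proteins gene63283 (3.13 ± 0.66) and gene70736 (2.75 ± 0.66) were higher and Helianthus_annuus_newGene_24716 was lower (-4.45 ± 0.36). That list call was lost without replicate 1 or 2 of 86-1 (0.0888 and 0.058) or replicate 1 or 2 of L-1-OL-1 (0.0626 and 0.058), and with median-of-ratios scaling (0.142) and quantile normalization (0.0975). In the oil body list 9 of 31 members were higher in 86-1 and 5 lower (9 and 5 adjusted over the list alone) (camera adjusted p = 0.0563). The oleosins gene29184 (8251 ± 527 against 734 ± 80.9, 3.49 ± 0.51) and gene77732 (2.46 ± 0.53) and the oil body-associated protein Helianthus_annuus_newGene_23526 (3.7 ± 0.22) were higher. In triacylglycerol assembly 7 of 26 members were higher in 86-1 and 5 lower (7 and 5 adjusted over the list alone) (camera adjusted p = 0.407), with the lysophosphatidyl acyltransferase gene55427 (2.94 ± 0.48) and gene31133 (3.48 ± 0.43) higher.

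In the seed storage list at 27 DAF 25 of 40 members were higher in 86-1 and 2 lower (29 and 2 adjusted over the list alone), with a median 3.26 above that of all genes. For the seed storage genes, camera gave an adjusted p = 7.77e-06, and an adjusted p = 0.742 with an estimated correlation. The 11S globulin gene27983 had 26385 ± 7630.3 against 2282 ± 1391 (3.66 ± 0.9). Its call was lost with no filter on low values (adjusted p = 0.202) and with quantile normalization (0.116). In carbon supply 21 of 44 members were higher in 86-1 and 4 lower (21 and 4 adjusted over the list alone). For the carbon supply genes, camera gave an adjusted p = 0.00166, and an adjusted p = 0.742 with an estimated correlation. They included the sugar transporter gene29703 (518 ± 77.8 against 4.47 ± 3.53, 6.85 ± 0.55), the cell wall invertase gene58278 (5.57 ± 0.45) and the sucrose synthase gene45459 (4.44 ± 0.83). Among flavonoid genes 15 of 26 members were higher in 86-1 and 2 lower (15 and 2 adjusted over the list alone). For the flavonoid genes, camera gave an adjusted p = 0.000354, and an adjusted p = 0.742 with an estimated correlation. The dihydroflavonol reductase gene57861 (509.7 ± 267 against 0.157 ± 0.0541, 8.6 ± 0.59) and the chalcone synthase gene53194 (5.2 ± 0.6) were higher. Of the hull markers of secondary wall and lignin 24 of 45 members were higher in 86-1 and 4 lower (24 and 4 adjusted over the list alone). For the wall and lignin genes, camera gave an adjusted p = 3.83e-05, and an adjusted p = 0.742 with an estimated correlation. The methyltransferases gene16817 (98.6 ± 24.2 against 3.13 ± 0.178, 4.56 ± 0.36) and gene54285 (2.61 ± 0.51) were higher. The laccase gene65042 was at 53.4 ± 4.45 in 86-1 and listed at 0 in every L-1-OL-1 library. For lipoxygenases 6 of 13 members were higher in 86-1 and 1 lower (8 and 1 adjusted over the list alone), with gene57443 higher (4.26 ± 0.62). For the lipoxygenase genes, camera gave an adjusted p = 0.0239, and an adjusted p = 0.742 with an estimated correlation.

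In the cytosolic ribosomal protein list at 27 DAF 4 of 79 members were higher in 86-1 and 32 lower (4 and 32 adjusted over the list alone). For the ribosomal protein genes, camera gave an adjusted p = 0.00571, and an adjusted p = 0.833 with an estimated correlation. The call was lost with quantile normalization (adjusted p = 0.232). Among them gene35835 was lower (-1.44 ± 0.3) and gene46722 higher (3.62 ± 0.36). In the cell cycle list 45 of 243 members were higher in 86-1 and 29 lower (37 and 26 adjusted over the list alone). For the cell cycle genes, camera gave an adjusted p = 0.0239, and an adjusted p = 0.851 with an estimated correlation. This call was lost without 86-1 replicate 1 (adjusted p = 0.0557), with median-of-ratios scaling (0.0688), with quantile normalization (0.0802) and with a pseudocount of 5 (0.0645). Of the heat shock genes 18 of 130 members were higher in 86-1 and 47 lower (18 and 47 adjusted over the list alone) (camera adjusted p = 0.0981), with gene58057 lower (-1.91 ± 0.34). Of the LEA genes 19 of 69 members were higher in 86-1 and 12 lower (19 and 12 adjusted over the list alone) (camera adjusted p = 0.122). There gene28892 was lower (318 ± 58.7 against 3719.9 ± 479.8, -3.55 ± 0.78) and the seed maturation protein gene6880 higher (137 ± 62 against 0.224 ± 0.0696, 6.73 ± 0.4). For lipid breakdown 0 of 15 members were higher in 86-1 and 3 lower (0 and 2 adjusted over the list alone) (camera adjusted p = 0.15), with the acyl-CoA oxidase gene46999 lower (-1.95 ± 0.42). Of the seed maturation regulators 1 of 6 members was higher in 86-1 and 2 lower (1 and 2 adjusted over the list alone) (camera adjusted p = 0.892), with a median of -0.31, a mean of 0.42 and a test pointing down. The LEC1-like gene73129 had 21.8, 26.3 and 6.56 FPKM in 86-1 and was listed at 0 in every L-1-OL-1 library.

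Genes with large differences outside the lists at 27 DAF were a galactose oxidase/kelch protein, gene71046 (706 ± 137 against 0.0975 ± 0.169, 9.32 ± 0.59), and the sugar transporter gene33431 (709 ± 157 against 0.241 ± 0.385, 9.18 ± 0.8), both higher in 86-1. The glucose/ribitol dehydrogenase gene49859 (0.368 ± 0.305 against 283 ± 55.4, -7.7 ± 0.57) and the berberine-family oxidoreductase gene34506 (-7.5 ± 0.77) were lower. limma called 14485 genes at 27 DAF, 6361 higher and 8124 lower in 86-1, and 11270 differed at least 2-fold. The share of higher genes was 43.9%, against 52.1% with median-of-ratios scaling and 50.2% without 86-1 replicate 1. With only genes of a mean FPKM of at least 5 the count was 7003. All 37 called genes likewise chosen kept their call without any 1 library. Across genes, the cultivar differences at 17 and 27 DAF correlated with Pearson's r = 0.506 and Spearman's rho = 0.473 (genes are not independent replicates). At both stages 2704 genes were higher and 2211 lower in 86-1, against 993 and 927 for independent lists.

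Between 17 and 27 DAF, in the comparison of fast with level oleic acid accumulation within 86-1, genes moved both ways. The dehydrin gene55914 rose from 0.367 ± 0.27 to 978 ± 562 FPKM (log2 difference 9.34 ± 1.23, adjusted p = 0.000504), and the oleosin gene11149 from 1.02 ± 1.15 to 2264 ± 1708 (10 ± 1.44, adjusted p = 0.000853). The histone H2A gene25026 fell from 547 ± 236 to 73.9 ± 6.16 (-2.77 ± 0.52), and the sucrose synthase gene45459 from 1494 ± 438 to 79.9 ± 36.8 (-4.3 ± 0.83). The acyl carrier protein gene63283, which carries growing fatty acid chains, fell from 1188 ± 253 to 164 ± 80.8 (-2.98 ± 0.66). The oleate desaturase gene64287 was at 695 ± 212 and 433 ± 223 (-0.82 ± 0.76, adjusted p = 0.534) and did not pass.

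In 86-1, 3 of the 5 omega-6 desaturases fell and none rose, over all genes and adjusted over the list alone (camera adjusted p = 0.0716). These were gene18808, from 254 ± 282 to 0.0811 ± 0.0727 (-6.29 ± 1.49), gene55389 (-2.31 ± 0.54) and gene1458 (-2.53 ± 0.81), while gene44739 had -0.5 ± 0.3 (adjusted p = 0.301). The call of gene18808 was lost without 17 DAF replicate 2 or 3 (adjusted p = 0.0624 and 0.0615). That of gene55389 was lost without these (0.0592 and 0.0581) or 27 DAF replicate 1 (0.0527). That of gene1458 was lost without 17 DAF replicate 2 or 3 (0.145 and 0.18) or 27 DAF replicate 1, 2 or 3 (0.158, 0.13 and 0.0558), with no filter (0.088) and with pseudocounts of 0.1 and 5 (0.0531 and 0.0574). The stearoyl-ACP desaturases gene3372 (-2.45 ± 0.93, adjusted p = 0.0904) and gene48724 (-0.71 ± 0.39, adjusted p = 0.256) did not pass, though gene3372 did in a fit of these 6 libraries (0.0354). Outside the lists, 3 genes with a fatty acid desaturase match fell. gene54857 went from 1232 ± 1356 to 1.04 ± 1.8 (-8.15 ± 1.47), gene24698 from 616 ± 736 to 0.196 ± 0.0975 (-7.36 ± 1.44) and gene54855 from 374 ± 435 to 0.103 ± 0.0167 (-7.06 ± 1.07). In plastid fatty acid synthesis 9 of 26 members fell and 0 rose (16 and 0 adjusted over the list alone). For the fatty acid synthesis genes, camera gave an adjusted p = 0.004, and an adjusted p = 0.742 with an estimated correlation.

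In the cell cycle and histone list of 86-1 138 of 243 members fell and 2 rose (160 and 3 adjusted over the list alone), with a median of -1.33 relative to all genes. For the cell cycle genes, camera gave an adjusted p = 7.5e-16, and an adjusted p = 0.742 with an estimated correlation. They included the histones gene35308 (-2.96 ± 0.63) and gene32184 (-4.59 ± 0.82). Of the cytosolic ribosomal protein genes 64 of 79 members fell and 1 rose (69 and 1 adjusted over the list alone). For the ribosomal protein genes, camera gave an adjusted p = 4.19e-12, and an adjusted p = 0.771 with an estimated correlation. One of them, gene52859, rose (4.17 ± 0.73). gene43564 fell (-1.59 ± 0.4), a call lost without 17 DAF replicate 2 or 3 (adjusted p = 0.0773 and 0.0554) or 27 DAF replicate 1 or 2 (0.0622 and 0.0538) and with median-of-ratios scaling (0.0608). For glycolysis 34 of 113 members fell and 0 rose (39 and 1 adjusted over the list alone). For the glycolysis genes, camera gave an adjusted p = 0.00233, and an adjusted p = 0.833 with an estimated correlation. The enolase gene25883 (-3.1 ± 0.44) and the phosphoglycerate kinase gene23034 (-2.41 ± 0.47) fell. In carbon supply 4 of 44 members rose and 4 fell (4 and 4 adjusted over the list alone) (camera adjusted p = 0.134), with a median of -0.04, a mean of -0.01 and a test pointing up. The sucrose synthase gene50241 fell (-2.21 ± 0.46) and its relative gene148 rose (4.39 ± 0.75). For secondary wall and lignin 15 of 45 members fell and 3 rose (17 and 4 adjusted over the list alone) (camera adjusted p = 0.172). The laccase gene31307 went from 52 ± 17.5 to 0, 0 and 0.0512 FPKM.

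In the LEA list of 86-1 26 of 69 members rose and 6 fell (28 and 9 adjusted over the list alone). For the LEA genes, camera gave an adjusted p = 5.67e-08, and an adjusted p = 0.742 with an estimated correlation. They included gene42840 (704 ± 481 to 4420.2 ± 842, 2.84 ± 0.59) and the seed maturation protein gene24265 (3.75 ± 0.66). The call of gene42840 was lost with no filter on low values (adjusted p = 0.0692) and with quantile normalization (0.0771). In the oil body list 10 of 31 members rose and 2 fell (12 and 3 adjusted over the list alone), with the oleosin gene67185 going from 702 ± 438 to 8481 ± 3031 (3.7 ± 0.62). For the oil body genes, camera gave an adjusted p = 1.3e-05, and an adjusted p = 0.742 with an estimated correlation. For seed storage 7 of 40 members rose and 3 fell (8 and 4 adjusted over the list alone). For the seed storage genes, camera gave an adjusted p = 1.82e-05, and an adjusted p = 0.742 with an estimated correlation. They included gene69051 (3.97 ± 0.49) and gene2767 (5.38 ± 0.49), both of the bifunctional inhibitor and lipid-transfer type. In lipid breakdown 4 of 15 members rose and 0 fell (4 and 0 adjusted over the list alone). For the lipid breakdown genes, camera gave an adjusted p = 0.000818, and an adjusted p = 0.832 with an estimated correlation. Of the glyoxylate cycle, the isocitrate lyase gene15722 rose from 4.5 ± 2.74 to 622 ± 214 (6.88 ± 1.43). The malate synthase gene22141 rose too (5.56 ± 1.3), a call lost without 17 DAF replicate 2 or 3 (adjusted p = 0.054 and 0.0584).

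Of the heat shock genes of 86-1 21 of 130 members rose and 16 fell (28 and 22 adjusted over the list alone), and the list's median was -0.12 and its mean 0.44. For the heat shock genes, camera gave an adjusted p = 0.00677, and an adjusted p = 0.833 with an estimated correlation. Among them gene28728 (7.78 ± 1.49), gene65080 (6.63 ± 1.2) and gene50436 (6.73 ± 0.79) rose. For photosynthesis 5 of 79 members rose and 1 fell (2 and 1 adjusted over the list alone), with gene46194 (3.02 ± 0.55) and the chlorophyll-binding gene890 (3.06 ± 0.44) higher at 27 DAF. For the photosynthesis genes, camera gave an adjusted p = 1.62e-06, and an adjusted p = 0.833 with an estimated correlation. For cuticle and wax 3 of 25 members rose and 3 fell (4 and 4 adjusted over the list alone). For the cuticle and wax genes, camera gave an adjusted p = 0.00605, and an adjusted p = 0.833 with an estimated correlation. That call was lost with only genes of a mean FPKM of at least 5 (adjusted p = 0.475). The lipoxygenase gene8063 rose (2.2 ± 0.36), and in its list 3 of 13 members rose and 4 fell (3 and 4 adjusted over the list alone) (camera adjusted p = 0.676). The medians of the lipoxygenase (-0.22) and flavonoid lists (-0.22) were below 0 while their tests pointed up. The means were 0.11 for the lipoxygenases and -0.29 for the flavonoid genes, of which 5 of 26 members fell and 3 rose (6 and 4 adjusted over the list alone) (camera adjusted p = 0.676). Triacylglycerol assembly had a median of 0.15, a mean of -0.01 and a test pointing up, and 5 of 26 members fell and 2 rose (6 and 2 adjusted over the list alone) (camera adjusted p = 0.272). The omega-3 desaturases had a median of -0.16, a mean of -0.15 and a test pointing up, and 1 of 4 members fell and 1 rose (1 and 1 adjusted over the list alone) (camera adjusted p = 0.915).

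Outside the lists, the lipid-transfer protein gene62341 rose from 383 ± 625 to 12978 ± 3276 (7.58 ± 1.4) and the reversibly glycosylated polypeptide gene58109 fell from 518 ± 362 to 0.508 ± 0.46 (-8.08 ± 0.85). limma called 5633 genes in 86-1, 1388 higher and 4245 lower at 27 DAF, and 4598 changed at least 2-fold. The share of higher genes among the calls was 24.6%, against 44.6% with median-of-ratios scaling and 51.1% with quantile normalization. The count was 2747 without 17 DAF replicate 2, 2996 without 17 DAF replicate 3, 3337 without 27 DAF replicate 1 and 2820 with only genes of a mean FPKM of at least 5. With the mean LEA level as a covariate it was 3200, and the calls of the cell cycle, ribosomal, glycolysis, lipid breakdown, photosynthesis and cuticle lists were lost (adjusted p from 0.052 to 0.903). That level did not overlap between the stages of 86-1 (3.57 to 3.77 and 4.76 to 5.45), so the covariate also takes out the stage difference itself. Of the 35 called genes chosen here, 30 kept their call without any 1 library and 10 with that covariate.

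In L-1-OL-1, in the same comparison of stages, albumin-8, gene47905, fell from 13173 ± 13186 to 1.95 ± 1.65 FPKM (log2 difference -10.92 ± 1.3, adjusted p = 7.61e-05), with 17 DAF values of 26758, 12336 and 425 in replicates 1, 2 and 3. The 11S storage protein gene16083 fell from 2519.5 ± 3498 to 0.256 ± 0.113 (-8.68 ± 1.53). The oleate desaturase gene64287 fell from 23.3 ± 23.8 to 0.0546 ± 0.048 (-3.83 ± 0.76, adjusted p = 0.002). Both tested stearoyl-ACP desaturases fell, gene3372 from 383 ± 495 to 5.16 ± 1.78 (-4.87 ± 0.93) and gene48724 from 95.2 ± 60.8 to 11 ± 1.8 (-2.82 ± 0.39). The LEA gene gene16284 rose from 30.3 ± 26.3 to 1572 ± 55.6 (5.96 ± 0.52).

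In L-1-OL-1 gene64287 alone among the 5 omega-6 desaturases passed (camera adjusted p = 0.306), over all genes and adjusted over the list alone. Changes of gene18808, gene55389, gene1458 and gene44739 were -1.83 ± 1.49, -0.38 ± 0.54, -1.32 ± 0.81 and -0.11 ± 0.3, with adjusted p from 0.208 to 0.813, and gene1458 passed without 17 DAF replicate 1 (0.0058). In plastid fatty acid synthesis 16 of 26 members fell and 3 rose (17 and 3 adjusted over the list alone). For the fatty acid synthesis genes, camera gave an adjusted p = 0.00215, and an adjusted p = 0.742 with an estimated correlation. The acyl carrier proteins gene63283 (-3.62 ± 0.66) and gene70736 (-3.54 ± 0.66) and the dehydratase gene9482 (-4.38 ± 0.77) fell. The acyl-CoA synthetase gene43869 fell (-2.96 ± 0.22), and in its list 6 of 16 members fell and 1 rose (6 and 1 adjusted over the list alone) (camera adjusted p = 0.197). For triacylglycerol assembly 7 of 26 members fell and 3 rose (7 and 2 adjusted over the list alone) (camera adjusted p = 0.331), including gene55427 (-3.77 ± 0.48) and gene31133 (-3.51 ± 0.43). For oil bodies 9 of 31 members fell and 7 rose (10 and 7 adjusted over the list alone) (camera adjusted p = 0.632). The oleosin gene29184 (-2.08 ± 0.51) and the caleosin gene80552 (-3.09 ± 0.43) fell. The call of gene29184 was lost in a fit of these 6 libraries alone (adjusted p = 0.143) and with no filter on low values (0.115). Of the omega-3 desaturases 2 of 4 members fell and 0 rose (2 and 0 adjusted over the list alone) (camera adjusted p = 0.331), and in tocopherol synthesis 5 of 21 members fell and 2 rose (5 and 2 adjusted over the list alone) (camera adjusted p = 0.229).

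Of the seed storage genes of L-1-OL-1 20 of 40 members fell and 5 rose (22 and 5 adjusted over the list alone), with a median of -2.20. For the seed storage genes, camera gave an adjusted p = 0.000472, and an adjusted p = 0.742 with an estimated correlation. The 11S storage protein gene16080 fell (-4.32 ± 1.2), a call lost without 17 DAF replicate 2 (adjusted p = 0.0525), in a fit of these 6 libraries alone (0.109) and with no filter on low values (0.106). The albumin gene70268 rose from 57 ± 48.5 to 1399 ± 516 (5.68 ± 1.05). For flavonoid synthesis 16 of 26 members fell and 2 rose (18 and 2 adjusted over the list alone). For the flavonoid genes, camera gave an adjusted p = 2.57e-05, and an adjusted p = 0.742 with an estimated correlation. Among them gene57861 (-6.5 ± 0.59) and Helianthus_annuus_newGene_23641 (-5.39 ± 0.31) fell. In secondary wall and lignin 22 of 45 members fell and 1 rose (22 and 1 adjusted over the list alone). For the wall and lignin genes, camera gave an adjusted p = 1.12e-05, and an adjusted p = 0.742 with an estimated correlation. The methyltransferases gene16817 (-5.29 ± 0.36) and gene54285 (-3.17 ± 0.51) fell, and the laccase gene65042 went from 51.3 ± 15.3 FPKM to 0 in every library. Of the carbon supply genes 19 of 44 members fell and 4 rose (19 and 4 adjusted over the list alone). For the carbon supply genes, camera gave an adjusted p = 0.0225, and an adjusted p = 0.833 with an estimated correlation. They included gene45459 (-4.71 ± 0.83), gene29703 (-5.21 ± 0.55) and gene58278 (-6.09 ± 0.45). In glycolysis 47 of 113 members fell and 15 rose (49 and 16 adjusted over the list alone), with the isomerase gene26384 (-1.77 ± 0.33) and the enolase gene72676 (-4.23 ± 0.45). For the glycolysis genes, camera gave an adjusted p = 0.004, and an adjusted p = 0.833 with an estimated correlation. For lipoxygenases 7 of 13 members fell and 1 rose (7 and 1 adjusted over the list alone). For the lipoxygenase genes, camera gave an adjusted p = 0.0321, and an adjusted p = 0.742 with an estimated correlation. There gene57450 went from 21 ± 7.23 FPKM to 0 in every library, and gene8063 rose (1.56 ± 0.36). The list call was lost without 17 DAF replicate 2 (adjusted p = 0.0634).

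In the cell cycle list of L-1-OL-1 98 of 243 members fell and 20 rose (103 and 20 adjusted over the list alone). For the cell cycle genes, camera gave an adjusted p = 2.22e-05, and an adjusted p = 0.833 with an estimated correlation. The histone H2A gene32210 went from 102, 21.9 and 9.24 FPKM to 0 in every library. For ribosomal proteins 10 of 79 members rose and 5 fell (6 and 2 adjusted over the list alone) (camera adjusted p = 0.285), and gene42404 rose (1.42 ± 0.35). Of the heat shock genes 44 of 130 members rose and 21 fell (44 and 21 adjusted over the list alone). For the heat shock genes, camera gave an adjusted p = 0.0232, and an adjusted p = 0.833 with an estimated correlation. This call was lost without 27 DAF replicate 1 (adjusted p = 0.0708) and with quantile normalization (0.0946). In lipid breakdown 5 of 15 members rose and 0 fell (4 and 0 adjusted over the list alone), a call lost without 17 DAF replicate 1 (0.082) and with quantile normalization (0.137). For the lipid breakdown genes, camera gave an adjusted p = 0.0291, and an adjusted p = 0.833 with an estimated correlation. The malate synthase gene22141 rose (4.45 ± 1.3), a call lost in a fit of these 6 libraries alone (0.12). The isopropylmalate synthase gene64450, an enzyme of leucine synthesis that the words of the list took in, rose too (1.37 ± 0.32), and without it 4 of 14 members rose. For photosynthesis 22 of 79 members fell and 4 rose (13 and 2 adjusted over the list alone), a call lost without 17 DAF replicate 2 (0.0557) and with only genes of a mean FPKM of at least 5 (0.313). For the photosynthesis genes, camera gave an adjusted p = 0.00471, and an adjusted p = 0.833 with an estimated correlation. For cuticle and wax 8 of 25 members fell and 2 rose (13 and 3 adjusted over the list alone) (camera adjusted p = 0.162). LEA genes went both ways, as 18 of 69 members rose and 25 fell (20 and 25 adjusted over the list alone) (camera adjusted p = 0.901), with a median of 0.16 and a test pointing down. Of these gene42840 rose (2.53 ± 0.59), a call lost in a fit of these 6 libraries alone (adjusted p = 0.317) and with no filter on low values (0.065). The regulators had a median of 0.34, a mean of -0.38 and a test pointing up, and 1 of 6 members rose and 1 fell (1 and 2 adjusted over the list alone) (camera adjusted p = 0.743).

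Large changes in L-1-OL-1 were the rise of gene60588, with a catalase immune-responsive domain (5.98 ± 1.13), and the falls of the sugar transporter gene33431 (-8.06 ± 0.8), the carbonic anhydrase gene38651 (-7.89 ± 0.53) and the germin gene25932 (-7.8 ± 0.4). limma called 12799 genes, 6119 higher and 6680 lower at 27 DAF, and 9526 changed at least 2-fold. The share of higher genes was 47.8%, against 50.4% with equal totals, 52.2% with a pseudocount of 5, 59.6% with quantile normalization and 54.7% without 17 DAF replicate 3. With only genes of a mean FPKM of at least 5 the count was 7112. Without 17 DAF replicates 2 and 3, with 1 library left at that stage and the spread given by the other groups, it was 12382, and the photosynthesis, lipoxygenase and carbon supply calls were lost (adjusted p = 0.579, 0.119 and 0.0826). Of the 37 called genes chosen here, 36 kept their call without any 1 library and 33 in a fit of these 6 libraries. Across genes, the stage differences of the cultivars correlated with Pearson's r = 0.336 and Spearman's rho = 0.380 (genes are not independent replicates). In both cultivars 500 genes rose and 1870 fell, against 283 and 945 for independent lists.

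The interaction asked which genes changed differently between the stages in the cultivars, as the stage difference of 86-1 minus that of L-1-OL-1. For albumin-8, gene47905, the difference was 11.71 ± 1.84 (adjusted p = 0.00141). The oleosin gene71463 had 34.3 ± 6.57 and 598 ± 16.5 FPKM at 17 and 27 DAF in 86-1 and 102 ± 47.5 and 63.1 ± 7.62 in L-1-OL-1 (4.7 ± 0.44). The oleosin gene29184 had 3.64 ± 0.71 (not called with no filter on low values, adjusted p = 0.0868) and the sugar transporter gene29703 6.64 ± 0.78. The ribosomal protein genes gene75943 (-3.32 ± 0.53) and gene35835 (-2.1 ± 0.42) stood on the negative side.

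No omega-6 desaturase passed in the interaction, over all genes or adjusted over the list alone. The value of gene64287 was 3.02 ± 1.07 (adjusted p = 0.0635), and those of gene18808, gene55389, gene1458 and gene44739 were -4.45 ± 2.11, -1.93 ± 0.76, -1.21 ± 1.15 and -0.39 ± 0.43. gene64287 passed with a pseudocount of 0.1 (5.67, adjusted p = 0.0072), with equal totals (0.0383) and without 86-1 27 DAF replicate 3 (0.0401) or L-1-OL-1 17 DAF replicate 3 (0.00301). So did gene18808 without replicate 1 of either 17 DAF group (0.0136 and 0.0236) and gene55389 with quantile normalization (0.0348) and without 86-1 17 DAF (0.00977) or L-1-OL-1 27 DAF replicate 1 (0.0404). The stearoyl-ACP desaturase gene3372 had 2.41 ± 1.32 (adjusted p = 0.207) and passed without L-1-OL-1 17 DAF replicate 3 (0.0205). gene48724 passed (2.11 ± 0.56, adjusted p = 0.0193), a call lost without 86-1 27 DAF replicate 2 (0.0532) or L-1-OL-1 27 DAF replicate 3 (0.0524).

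For the seed storage list 13 of 40 members had a difference above 0 and 0 below (15 and 0 adjusted over the list alone), with gene2767 at 13.15 ± 0.7. For the seed storage genes, camera gave an adjusted p = 2.31e-08, and an adjusted p = 0.742 with an estimated correlation. In the oil body list 9 of 31 members had a difference above 0 and 0 below (10 and 0 adjusted over the list alone). For the oil body genes, camera gave an adjusted p = 0.000354, and an adjusted p = 0.742 with an estimated correlation. In carbon supply 10 of 44 members had a difference above 0 and 1 below (10 and 1 adjusted over the list alone), with the invertase gene58278 (6.12 ± 0.63) and the sucrose transporter gene15616 (2.89 ± 0.55). For the carbon supply genes, camera gave an adjusted p = 0.000683, and an adjusted p = 0.742 with an estimated correlation. In the LEA list 17 of 69 members had a difference above 0 and 4 below (20 and 4 adjusted over the list alone), among them gene78461 (5.28 ± 1.33) and gene75583 (4.72 ± 0.78). For the LEA genes, camera gave an adjusted p = 1.06e-05, and an adjusted p = 0.742 with an estimated correlation. For flavonoid synthesis 8 of 26 members had a difference above 0 and 1 below (9 and 1 adjusted over the list alone), with gene57861 (7.17 ± 0.83) and Helianthus_annuus_newGene_23641 (6.14 ± 0.44). For the flavonoid genes, camera gave an adjusted p = 7.91e-06, and an adjusted p = 0.742 with an estimated correlation. For secondary wall and lignin 15 of 45 members had a difference above 0 and 7 below (16 and 7 adjusted over the list alone), with gene16817 at 3.73 ± 0.51. For the wall and lignin genes, camera gave an adjusted p = 0.00407, and an adjusted p = 0.816 with an estimated correlation. The laccase gene65042 averaged 7.17 ± 9.54 and 53.4 ± 4.45 FPKM in 86-1 and 51.3 ± 15.3 and 0 in L-1-OL-1.

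Of the photosynthesis genes 12 of 79 members had a difference above 0 and 0 below (0 and 0 adjusted over the list alone). For the photosynthesis genes, camera gave an adjusted p = 1.24e-08, and an adjusted p = 0.833 with an estimated correlation. The chlorophyll-binding gene46351 (3.89 ± 1.03) lost its call without L-1-OL-1 17 DAF replicate 2 (adjusted p = 0.0546) or 27 DAF replicate 3 (0.0517). For ribosomal proteins 0 of 79 members had a difference above 0 and 37 below (1 and 44 adjusted over the list alone). For the ribosomal protein genes, camera gave an adjusted p = 2.31e-08, and an adjusted p = 0.833 with an estimated correlation. For cuticle and wax 5 of 25 members had a difference above 0 and 2 below (6 and 2 adjusted over the list alone), a call lost with only genes of a mean FPKM of at least 5 (0.244). For the cuticle and wax genes, camera gave an adjusted p = 0.00233, and an adjusted p = 0.816 with an estimated correlation. For lipoxygenases 3 of 13 members had a difference above 0 and 0 below (4 and 0 adjusted over the list alone), with gene57443 at 6.64 ± 0.87. For the lipoxygenase genes, camera gave an adjusted p = 0.0104, and an adjusted p = 0.742 with an estimated correlation. The other lists gave no interaction call, and the lowest camera adjusted p among them was 0.0526 for the cell cycle. Members that passed in them were the heat shock proteins gene58057 (-2.61 ± 0.48), gene19393 (-2.34 ± 0.45) and gene50436 (6.35 ± 1.12). Others were the acyl carrier protein gene32158 (2.58 ± 0.61), the acyltransferases gene31133 (6.43 ± 0.61) and gene50246 (-1.79 ± 0.43), the homogentisate phytyltransferase gene50785 of tocopherol synthesis (3.34 ± 0.59) and the acyl-CoA synthetase gene43869 (2.29 ± 0.31).

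Outside the lists, large positive interaction values were those of gene71046 (14.56 ± 0.84), the lipid-transfer protein gene62341 (13.17 ± 1.98) and the carbonic anhydrase gene38651 (9.95 ± 0.75). The COBRA-like gene5852 was at 45.6 ± 26.2 FPKM at 17 DAF and 0 at 27 DAF in 86-1, and at 27.3 ± 8.41 and 57 ± 6.14 in L-1-OL-1 (adjusted p = 4.04e-05). limma called 6634 genes, 2553 positive and 4081 negative, 6314 of them at least 2-fold. The share of positive calls was 38.5%, against 48.3% with median-of-ratios scaling and 48.9% with a pseudocount of 0.1. The count was 4025 without L-1-OL-1 17 DAF replicate 2, 4338 without 86-1 17 DAF replicate 2, 4389 without 86-1 27 DAF replicate 2 and 4342 without L-1-OL-1 27 DAF replicate 3. It was 10073 with quantile normalization and 3632 with only genes of a mean FPKM of at least 5. Of the 30 called genes chosen here, 28 kept their call without any 1 library. No list call in any of the 5 comparisons held with an estimated correlation, where the lowest adjusted p was 0.742.

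The endosperm and seed coat list and the abscisic acid list had 2 tested members each, too few for the list test. Both members of the first were higher in 86-1 at 17 and 27 DAF, both fell in 86-1 and 1 fell in L-1-OL-1. Of the second, 1 member was higher in 86-1 at 27 DAF, and in L-1-OL-1 1 rose and 1 fell.

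**Figure D3:**
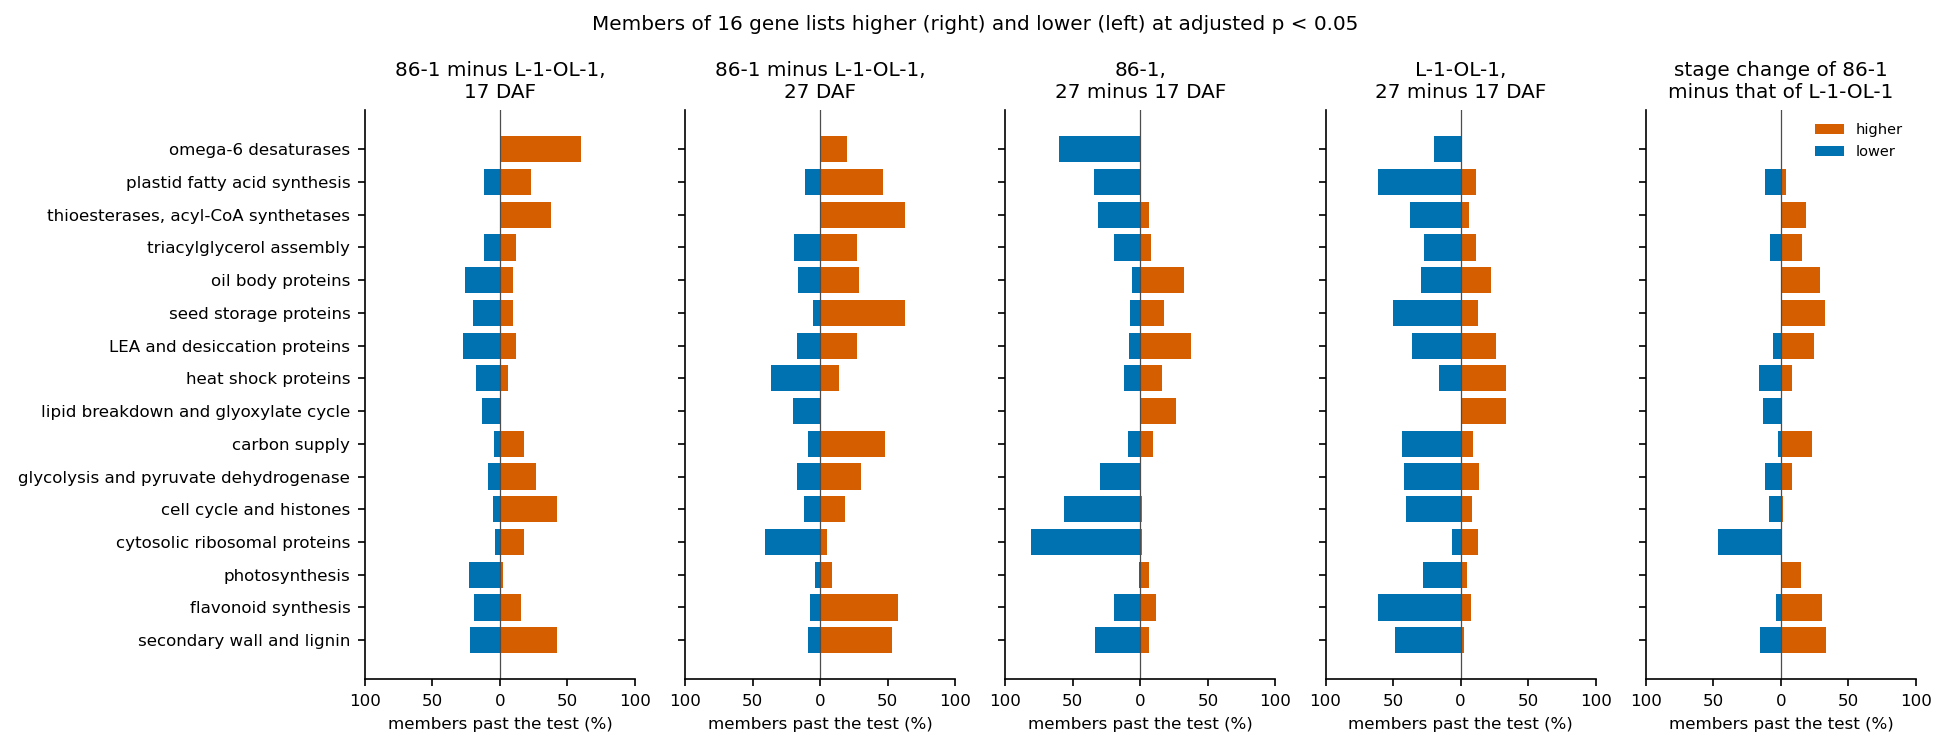
Members of 16 gene lists (% of the tested members of each list) that were higher (to the right) or lower (to the left) at an adjusted p under 0.05 in the 5 comparisons. Of the cytosolic ribosomal protein genes 64 of 79 fell in 86-1 and 5 fell in L-1-OL-1, and of the seed storage genes 25 of 40 were higher in 86-1 at 27 DAF.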

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

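The tests of seed maturity and of storage genes among the L-1-OL-1 libraries at 17 DAF, the ratio of genes expressed in 1 cultivar and the regroupings of libraries were set before their results were seen, while the tests of a swapped label, of gene64287 and of added gene models were chosen or changed after.

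A tested difference between the cultivars in the change from 17 to 27 DAF singled out the results that follow. It was called for 6634 genes by limma. By list, the median difference relative to all genes was 2.65 for seed storage proteins, 1.72 for photosynthesis, 1.31 for LEA proteins, 1.28 for flavonoid synthesis, 1.08 for oil body proteins and 1.01 for secondary wall and lignin. It was 0.88 for lipoxygenases, 0.73 for cuticle and wax, 0.71 for carbon supply and -1.41 for cytosolic ribosomal proteins. These list calls were made with camera's preset correlation, and with a correlation estimated by camera 0 of the 105 list tests over all contrasts passed (lowest adjusted p = 0.742, 4 at an unadjusted p under 0.05). The single genes listed here are the 62 of the 111 genes printed with the comparisons whose interaction was called, a chosen part of all called genes. Positive differences, in log2 units and with the stage change of 86-1 the higher one, were those of gene71046 (14.56), gene62341 (13.17), gene2767 (13.15), gene47905 (11.71), gene38651 (9.95), gene33431 (8.36), gene16083 (8.0), gene57861 (7.17), gene25932 (7.01), gene57443 (6.64), gene29703 (6.64) and gene31133 (6.43). Somewhat smaller positive values were those of gene50436 (6.35), Helianthus_annuus_newGene_23641 (6.14), gene58278 (6.12), gene57445 (5.91), gene69051 (5.74), gene63167 (5.71), gene55914 (5.61), gene18005 (5.46), gene16080 (5.33), gene78461 (5.28), gene75583 (4.72) and gene71463 (4.7). Next came gene80552 (4.42), gene50700 (4.07), gene6880 (3.96), gene46351 (3.89), gene16817 (3.73), gene29184 (3.64), gene50785 (3.34), gene67185 (3.26), gene53194 (3.03), gene15616 (2.89), gene890 (2.63) and gene32158 (2.58). The smallest positive values among the genes listed here were those of gene46194 (2.38), gene55427 (2.35), gene43869 (2.29), gene48724 (2.11) and gene72132 (1.7). Negative differences were those of gene34506 (-5.34), gene16284 (-3.79), gene75943 (-3.32), gene49859 (-3.05), gene42404 (-2.98), gene58057 (-2.61), gene19393 (-2.34), gene35835 (-2.1), gene43564 (-1.88), gene50246 (-1.79), gene64602 (-1.75), Helianthus_annuus_newGene_24716 (-1.66), gene74529 (-1.65) and gene64450 (-1.36). Of the genes listed here, 7 were listed at 0 in every library of a group, which leaves the size of the difference open, so only the adjusted p is given, for gene31307 (1.58e-05), gene54855 (0.0165), gene57450 (0.00317), gene5766 (8.8e-05), gene58109 (0.0111), gene5852 (4.04e-05) and gene65042 (0.000104).

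In regroupings that exchanged the cultivar labels within each stage, 7 of 100 draws, the real one included, called at least 6634 genes, and the highest other draw called 14579. That draw exchanged the cultivars at 27 DAF as a whole, which turns the interaction into the sum of both cultivar differences. Whether the other draws keep part of it was not checked, so this share decides nothing on chance for the interaction. For the other comparisons the 6 libraries make 10 splits, too few for a share under 0.05. The real split alone, 1 of 10, gave as many genes in each of them, with 8111 against at most 270 in the others at 17 DAF and 14485 against at most 0 at 27 DAF. The counts were 5633 against at most 1 in 86-1 and 12799 against at most 32 in L-1-OL-1.

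The first pattern weighed was the spread between the L-1-OL-1 libraries at 17 DAF, which enters both cultivar and stage differences. A swapped label with a 27 DAF library was argued against, because the highest r across genes of replicate 3 with those libraries (0.788) lay -0.158 from the lowest r among them (0.947). Storage genes taking much of the FPKM are argued against as the whole cause, as rescaling other genes alike would not lower r to 0.784. The LEA median (0.67, replicate 3 minus 1 after median-of-ratios scaling) lay between its set bounds. A different seed maturity in the 3 libraries is a candidate, since replicate 3 minus replicate 1 correlated across genes with the stage difference of 86-1 (r = 0.569, and 0.537 for replicate 2, over the same replicate 1). Storage genes fell from replicate 1 to 3 (median -4.29 after median-of-ratios scaling), as in the stage change of L-1-OL-1 (relative median -2.2, over the same libraries) and unlike that of 86-1 (0.76), so maturity stays open, as does a different mix of seed tissues, which was not tested.

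The second pattern was the lower gene64287 level in L-1-OL-1. More advanced L-1-OL-1 seeds stay open. 86-1 at 27 DAF exceeded L-1-OL-1 at 17 DAF by 4.67 ± 0.76 log2 units (adjusted p = 0.000626). The LEA median (0.12 apart) rose 0.16 by 27 DAF in 86-1, so it cannot show equal maturity. Reads moved to other omega-6 desaturases were argued against, because the summed FPKM of the list was also lower, with 944, 983 and 1157 in 86-1 and 98.3, 75.4 and 109.9 in L-1-OL-1 at 17 DAF (log2 ratio 3.44). A sequence difference of L-1-OL-1 from the reference that loses reads cannot be told apart from lower expression, because the interaction of the gene with a pseudocount of 0.1 (5.67, adjusted p = 0.0072) decides nothing where 22.1% of genes had an interaction. A genetic cause of lower expression in L-1-OL-1 stays open as an untested hypothesis.

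The third pattern was genes expressed in 1 cultivar, with an FPKM of at least 5 in all its libraries and at most 0.1 in all of the other. At 17 DAF there were 150 in 86-1 and 14 in L-1-OL-1, a ratio of 10.7, at 27 DAF 288 and 473, and at both stages 93 and 2. Loss of expression in L-1-OL-1 at 27 DAF is argued against as the whole cause, since the excess was found at 17 DAF, and the counts at 27 DAF lay the other way. Added gene models may account for part of these genes, as they made up 66% of the 150 and 19.8% of the tested genes (Fisher's exact p = 6.65e-35, genes are not independent replicates). At 27 DAF they made up 36.5% of the 288 genes in 86-1 and 69.8% of the 473 in L-1-OL-1, so the excess in 86-1 at 17 DAF stays open, as does the presence of genes in 1 genome only.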

How the results depend on the processing

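The alternatives without L-1-OL-1 17 DAF replicates 2 and 3 and with the LEA covariate were chosen after seeing the data, and the first leaves 1 library in that group, with the spread taken from the other groups. Counts of genes are compared here with 8111 and 14485 for the cultivar differences at 17 and 27 DAF, 5633 and 12799 for the stage differences in 86-1 and L-1-OL-1, and 6634 for the interaction. With a mean FPKM of at least 5, where 15181 genes were tested, they were 2300, 7003, 2820, 7112 and 3632. The 17 DAF count was 5137 with only its libraries, 3768 without L-1-OL-1 replicates 2 and 3 and 4637 with the LEA covariate, the count in 86-1 was 3200 with that covariate, and the interaction count was 10073 with quantile normalization. Leaving out 1 library gave 5448 to 12295 at 17 DAF, 11753 to 13861 at 27 DAF, 2747 to 7576 in 86-1, 9549 to 13561 in L-1-OL-1 and 4025 to 9406 in the interaction. Pseudocounts, no filter, no trend, equal totals and median-of-ratios scaling left all 5 counts within 1.5 times.

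The larger side of the calls turned in alternatives set beforehand. These were 17 DAF without L-1-OL-1 replicate 1, 27 DAF with median-of-ratios scaling and without 86-1 replicate 1, and 86-1 with quantile normalization. In L-1-OL-1 they were a pseudocount of 5, equal totals, quantile normalization and the fit without 17 DAF replicate 3. Among lists and named genes called in at least 1 of the fits compared, directions turned only in the added alternatives, while fry turned some lists called in neither. The LEA level did not overlap between the stages of 86-1 or between the cultivars at 17 DAF, so that covariate also takes out part of these differences. Without L-1-OL-1 17 DAF replicates 2 and 3 the relative medians of ribosomal proteins were 0.000169 at 17 DAF and -0.597 in L-1-OL-1, that of photosynthesis in L-1-OL-1 0.34 and that of the cell cycle in the interaction 0.0299, and gene65080 was 0.18 at 17 DAF. With the LEA covariate the lists' own medians at 17 DAF were 0.14 for ribosomal proteins and -0.0488 for plastid fatty acid synthesis. In 86-1 they were -0.65, -1.27 and -0.27 for ribosomal proteins, photosynthesis and plastid fatty acid synthesis. In the interaction they were 0.0136 and -1.1 for the cell cycle and lipid breakdown. All tested genes had medians of 0.36 at 17 DAF, -0.65 in 86-1 and -0.56 in the interaction with this covariate. Single genes were 0.301 for gene65080, 0.14 for gene27200 and -0.17 for gene3372 at 17 DAF, and -0.41 for gene10240, -0.14 for gene38953, 0.0804 for gene70736 and 0.17 for gene9482 in 86-1. For ribosomal proteins at 17 DAF and for ribosomal proteins and plastid fatty acid synthesis in 86-1 the test turned while the median kept its sign. The cause was not tested.

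Of 352 gene results, 331 stayed on their side of the threshold with median-of-ratios scaling and 21 lost a call, and 28 lost and 1 gained a call with quantile normalization. No filter ended 52 calls, a fit of only the compared groups 53 and the LEA covariate 91. Of 105 list results, the estimated correlation ended 46 calls and fry ended 22 and added 8. Replicates share only a number. In the check of pairing, 18 pairs of libraries with the same number had correlations of their deviations from -0.226 to 0.459, 4 of them over 0.1, and 6 of 12 libraries lay closest to their own number. With the replicate block the counts were 8472, 15832, 6539, 14265 and 8165, and gene64287 and gene55389 passed in the interaction (adjusted p = 0.024 and 0.0221). edgeR and DESeq2 were listed as alternatives and not run, because the values are not counts. Depth is known only in relative terms, so an FPKM near 0 is not read as absence of a transcript.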

Other observations

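All family tests here were chosen after the data were seen, by grouping genes with the same description, and cover 303 families with at least 10 tested members (1515 tests). With a correlation estimated by camera 0 of the 1515 tests passed (lowest adjusted p = 0.837), and 45 had an unadjusted p under 0.05.

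Cystatins, inhibitors of cysteine proteases, were higher in 86-1 at 17 DAF for 12 of 15 members and lower for 0, with a median 3.5 above that of all genes (adjusted p = 0.999 with an estimated correlation). In 86-1, 9 of them fell by 27 DAF and 0 rose, and in the interaction 10 lay below 0 and 1 above. Of 27 cupredoxins, small copper proteins of the cell surface, 19 were higher and 3 lower in 86-1 at 17 DAF. At 27 DAF, 9 of 11 SWEET sugar transporters were higher in 86-1 and 0 lower (relative median 2.83), as were 18 of 27 GDSL lipases (1 lower), 10 of 15 peroxidases (0 lower) and 26 of 45 heavy metal-associated domain proteins (4 lower). In L-1-OL-1, 5 of these SWEET genes, 18 of the lipases, 9 of the peroxidases and 28 of the metal-associated proteins fell between the stages.

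Of 14 Aux/IAA proteins, repressors of the auxin response, 11 were higher and 0 lower in 86-1 at 27 DAF, and 12 fell in L-1-OL-1 and 8 in 86-1. Of 57 NAC transcription factors 20 were higher and 6 lower in 86-1 at 27 DAF, and 27 fell and 4 rose in L-1-OL-1. Of 13 TIFY proteins, repressors in jasmonate signalling, 10 fell and 1 rose in L-1-OL-1 (relative median -2.26), and of 34 aquaporins 20 fell and 3 rose (relative median -1.54). Pentatricopeptide repeat proteins, which process organelle RNA, went the other way, as 35 of 88 rose and 0 fell in L-1-OL-1 (53 rose with median-of-ratios scaling and 68 with quantile normalization) and 42 were lower and 2 higher in 86-1 at 27 DAF. These directions were the same with equal totals, median-of-ratios scaling and quantile normalization.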
